A study of Homo sapiens with 6 samples.

How the data were processed

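Total RNA of 6 U87 samples, 3 control and 3 ROCK1 knockdown, was measured 24 h after siRNA transfection on 1-colour Agilent arrays labelled with Cy3. Groups and replicate numbers came from the sample labels. The deposited scanner files hold intensity values per spot. Per the file headers, they were made with Agilent Feature Extraction 10.7.3.1, and the processed signal was background-subtracted and detrended within the array. A value table on a log2 scale was also deposited; each of its columns correlated at over 0.999 with the log2 median spot signal of its own array. The medians of its columns were 6.89, 6.89, 6.89, 6.89, 6.90 and 6.89. How the authors centred the values is not given in the sources used here. It was used only as an alternative. The gene positions of the array design are on hg19.

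The main values were log2 of the processed signal minus each array's 75th percentile over the probes outside the control features. Control spots and spots flagged as outliers were left out (419 to 562 spots per array), and the spots of a probe were averaged. Probes were kept when well above background on all 3 arrays of at least 1 group, which left 23838 of 42405. The array's RefSeq accessions were matched, without versions, to a RefSeq gene table of GRCh38.p14, used for names only: 25422 probes received a symbol and 16983 kept the file's name. A gene was represented by its kept probe with the highest mean over the 6 arrays. On the median spot, the signal was 2.74 to 3.29 times that of the negative control spots.

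Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, knockdown minus control, no block), with Benjamini-Hochberg adjustment over all genes. The test of ROCK1 alone was a two-sided exact permutation test. The 31 gene lists, with 1076 genes of which 950 were tested, were written before the data were examined, as were the tests, the groups and the rule for named genes. Lists with at least 5 tested members were tested with camera at its preset correlation of 0.01, adjusted over the lists. The rule names ROCK1 and ROCK2; of the genes that passed, whose groups do not overlap and whose symbol is not an accession, clone or open reading frame name, the 12 largest rises and the 12 largest falls; and from each list up to 3 members with the smallest p. The text names some of these list members; 2 of the 12 rises, 1 list and some list members are not reported here. The 4 largest falls of the genes that passed, all without a symbol, were chosen after their values were seen. Groups did not overlap for 6750 genes (34.5%, where chance gives 10%), and 4572 genes had an unadjusted p under 0.05.

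The fit was tested on 20 sets of simulated arrays with 19574 genes, 3 against 3, with independent noise and 200 changed genes in each. It called 2.54% of genes changed 1.5-fold, 46.0% of those changed 2-fold and 94.9% of those changed 4-fold, and 6.35% of the calls were unchanged genes. A list shifted by 0.32 log2 was called in 100% of the sets and no unshifted list was. The simulated genes were not correlated, so this cannot show how often lists of correlated genes would be called by mistake. The simulated shift was also larger in size than the median of each list called in the data. Each simulated gene had the same noise on all 6 arrays, whereas in the data knockdown replicate 3 stood apart. The shares of genes called may therefore not hold for these data.

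The alternatives were normexp background correction (offset 50), quantile normalization, median centring, the deposited value table, no filter and a filter on all 6 arrays, the mean over a gene's probes, a variance trend with robust estimation, array weights, a replicate block, each sample left out, other thresholds, every probe on its own, and camera with an estimated correlation and fry. Normexp used the median spot signal in place of the mean spot signal. All arrays shared 1 slide and 1 scan, so neither could be a block. Leaving out the bottom rows and the strip of columns, the slide row as a block, and leaving out these parts together with knockdown replicate 3 were chosen after seeing the data.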

Results

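RNA was profiled in U87 cells, an established human glioblastoma line, 24 h after reverse transfection with siRNA. There were 3 control samples and 3 samples with siRNA against ROCK1, the gene of a serine/threonine kinase that acts on the actin cytoskeleton. Each sample was hybridised alone, in 1 colour, to an Agilent array with 42405 distinct probes outside the control features. Between 23671 and 25930 probes were well above background on an array (55.8% to 61.1%), and no spot was saturated. After probes were assigned to genes, 19574 genes and transcripts were tested, of which 13393 had a gene symbol. No label says that the samples of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision.

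The comparison asks what differed between cells with siRNA against ROCK1 and control cells. With no further knockdown group or rescue, effects of the siRNA on other genes cannot be told apart from effects of ROCK1 loss. ROCK1 itself was lower on all 3 knockdown arrays. Its brightest probe (A_24_P538403, for transcript NM_005406) read 1.29 ± 0.09 (SD, n = 3) in the controls and -1.42 ± 0.29 (SD, n = 3) in the knockdown, in log2 relative to the array's 75th percentile. This was a fall of 6.55-fold (log2 fold change -2.71, SE 0.17, 95% interval -3.12 to -2.30), with 15.3% of the control level left. Single knockdown arrays held 13.3%, 13.9% and 19.2% of the control mean. The other ROCK1 probe (A_23_P130429) was 5.73-fold lower, at -0.67, -0.66 and -0.56 in the controls and -3.16, -3.44 and -2.84 in the knockdown. The adjusted p of ROCK1 was 0.00757 (limma, Benjamini-Hochberg). It did not pass in some alternatives, with 0.0917 without control replicate 3 and 0.16 with the replicate block (limma). The two-sided exact permutation test of the brightest probe gave p = 0.1, the smallest that 3 samples against 3 allow. ROCK2, the gene of the paralogous kinase, did not pass the test on its brightest probe (log2 fold change 0.04, SE 0.23, adjusted p = 0.926 by limma); it read 0.05, -0.07 and 0.74 on the knockdown arrays, and its log2 fold change was -0.21 without knockdown replicate 3. The ROCK2 probes disagreed: the dimmer one (A_33_P3257140) read -1.53, -1.23 and -1.53 in the controls and -0.64, -0.92 and 0.18 in the knockdown (adjusted p = 0.14 by limma over all kept probes).

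**Figure D1:**
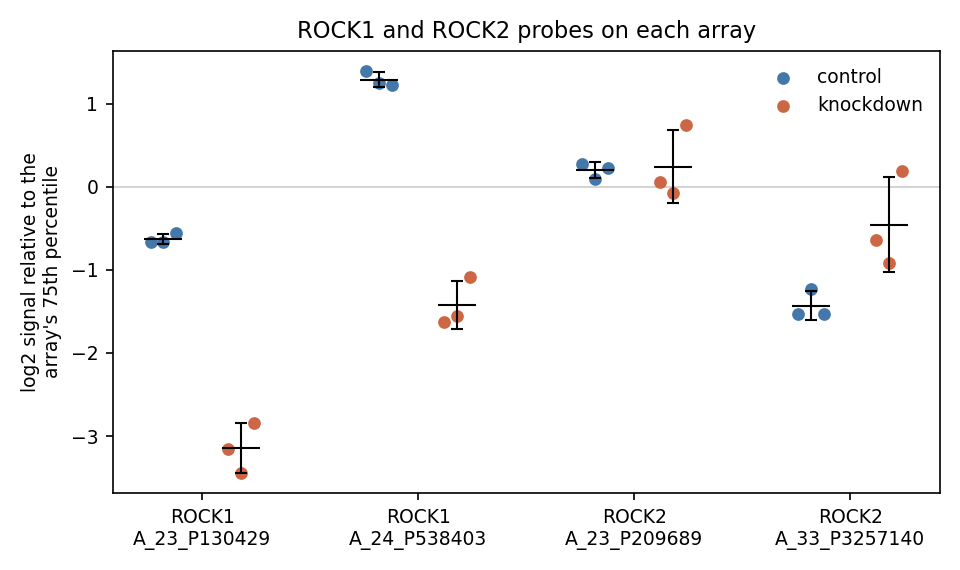
Log2 signal relative to the array's 75th percentile for the ROCK1 and ROCK2 probes, with a point per array and the mean and SD of the 3 arrays of a group. Both ROCK1 probes lie lower on every knockdown array, with 5.73-fold and 6.55-fold falls, while the ROCK2 probes differ from each other.

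Among all genes, 45 changed at an adjusted p under 0.05 in limma's moderated test, 17 of them higher and 28 lower in the knockdown. Changes of at least 2-fold made up 39 of these, 17 higher and 22 lower. Of the 45, 30 had a gene symbol. The zinc finger gene ZNF721 rose most among the named genes, by 4.17-fold (log2 2.06, SE 0.24), and ZNF616 rose 3.59-fold (log2 1.84, SE 0.15). HABP4, which encodes an RNA-binding and hyaluronan-binding protein, rose 3.03-fold. RGS19, a regulator of G-protein signalling, rose 2.68-fold. INSYN2A rose 2.61-fold and P2RY6, a receptor for extracellular nucleotides, also rose 2.61-fold. FGF14 rose 2.47-fold (log2 1.31, but 0.59 with normexp), THBS4, a thrombospondin, 2.21-fold, and the kinetochore gene ZW10 2.18-fold. ZNF875 read 2.38-fold higher, but it was not well above background on any control array, so its fold is uncertain. With normexp its log2 fold change was 0.26. Where a gene was not well above background on any array of a group, a more cautious fold was also computed. For it, those arrays were set at the lowest signal well above background where the probe lay below it. The control arrays of ZNF875 lay above that level, so its fold stayed the same and no lower bound is given for it. The adjusted p of these 10 genes lay between 0.0217 and 0.0499 (limma).

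The falls besides ROCK1 included EIF2S1, the alpha subunit of a translation initiation factor, which fell 3.14-fold (log2 -1.65, SE 0.13). TLNRD1, a talin rod domain gene, fell 2.84-fold (log2 -1.51, SE 0.14). SLC4A7, a bicarbonate cotransporter, fell 2.47-fold, and the cytokine gene LIF fell 2.44-fold. SECISBP2, needed to make selenoproteins, fell 2.39-fold, SLC67A2 fell 2.35-fold and the small GTPase gene RAB28 fell 2.25-fold. CEMIP2, SPRY1 and VPS37B fell 2.19-fold, 2.18-fold and 2.18-fold; SPRY1 (log2 -1.12, but -0.46 with normexp and -0.40 with the deposited values) encodes an inhibitor of receptor tyrosine kinase signalling and VPS37B a subunit of an endosomal sorting complex. The non-coding gene LINC01530 fell 3.33-fold (log2 -1.73, SE 0.21, but -0.87 with normexp), but its only spot lay in the bottom rows of the array, where falls of over 2 log2 were more frequent (3.49% of spots) than in the other rows (0.18%). The dimmer probes of LIF, SECISBP2, RAB28 and CEMIP2 were also lower in the knockdown but did not pass. The 12 named falls, ROCK1 included, had adjusted p between 0.00757 and 0.0499 (limma).

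**Figure D2:**
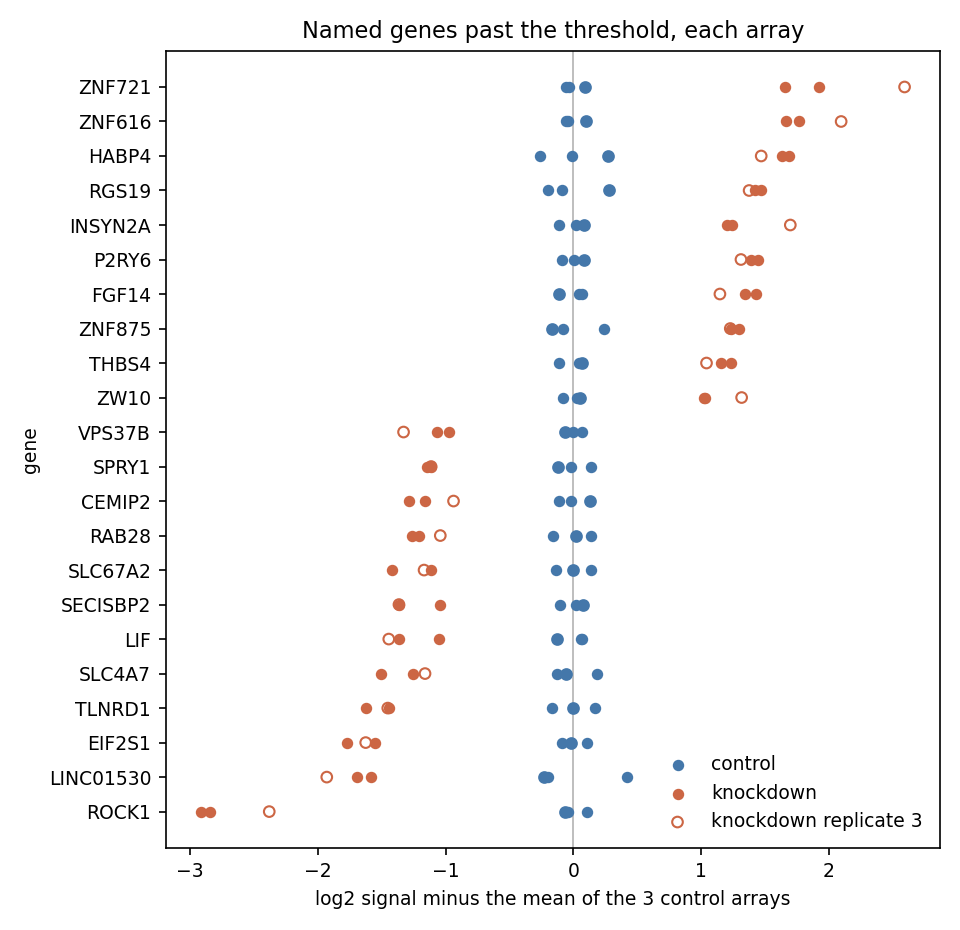
Log2 signal of each array minus the mean of the 3 control arrays for 10 genes with large rises and the 12 with the largest fall among those that passed. Filled points are single arrays and open points are ROCK1 knockdown replicate 3. Only genes whose 3 knockdown arrays lie on one side of the 3 control arrays could be chosen.

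Most calls sat close to the threshold, with 10 of the 45 under an adjusted p of 0.04 (limma), and the count changed whichever single array was left out. It was 224 without knockdown replicate 3 (77 higher, 147 lower, with all 45 among them). It was 3 and 2 without knockdown replicates 1 and 2, and 4, 5 and 2 without control replicates 1, 2 and 3. Fewer replicates can by themselves lower the count, so these low counts do not single out an array. The higher genes made up 37.8% of the calls here, 55.6% of 108 calls after quantile normalization and 65.4% of 26 calls after median centring, which moved the median of all genes from -0.02 to 0.17.

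Most genes of the 2 cell cycle lists lay higher in the knockdown. Of 54 G1/S and DNA replication genes, 48 had a fold change above 0 (median log2 0.21), with RRM1 at 0.55, POLA2 at 0.65 and POLE2 at 0.46. Of 60 G2/M and mitosis genes, 49 lay above 0 (median 0.20), with the centromeric histone gene CENPA at 0.91, CCNB2 at 0.48 and DLGAP5 at 0.59. Of 32 cholesterol synthesis genes, 23 lay below 0 (median -0.31), among them CYP51A1 at -0.96, LSS at -0.68 and MSMO1 at -0.95. Of 31 hypoxia targets, 27 lay below 0 (median -0.18), among them the glucose transporter gene SLC2A1 at -0.83, MXI1 at -0.76 and NDRG1 at -0.71. No member of these 4 lists passed over all genes. Adjusted over the list alone, 1 of the G2/M genes (CENPA) rose, 9 cholesterol genes and 2 hypoxia genes fell, and no G1/S gene passed. These 4 of 31 lists passed camera with its preset correlation, at adjusted p 3.33e-05, 8.88e-04, 0.00397 and 0.0258 in the order given. None passed with a correlation estimated from the data (adjusted p = 0.879 for each) or with fry (adjusted p = 0.457, 0.591, 0.457 and 0.591). In 6 of the 10 splits of the 6 samples into 3 and 3, the real one included, camera called at least 4 lists. Camera called 1 to 6 lists when single arrays were left out, with the lowest count without control replicate 2, where only the G1/S list passed. The G1/S list passed whichever single array was left out, and the G2/M list failed only without control replicate 2. The cholesterol list also lost its call without knockdown replicate 1 or 2, and the hypoxia list without knockdown replicate 1 or 2 or control replicate 3. In the median of the G2/M list, control replicate 1 lay 0.27 above the control mean. The knockdown arrays lay at 0.14, 0.16 and 0.33, so the groups overlap. Without control replicate 1 the G2/M median was 0.32. In the hypoxia list the control arrays read -0.19, 0.07 and 0.14 and the knockdown arrays -0.32, -0.29 and -0.13, so the groups overlap; its median was -0.31 without knockdown replicate 3 and -0.34 without control replicate 1. After median centring only the 2 cell cycle lists passed, with medians of 0.40 and 0.39, and the cholesterol and hypoxia medians were -0.12 and 0.01.

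**Figure D3:**
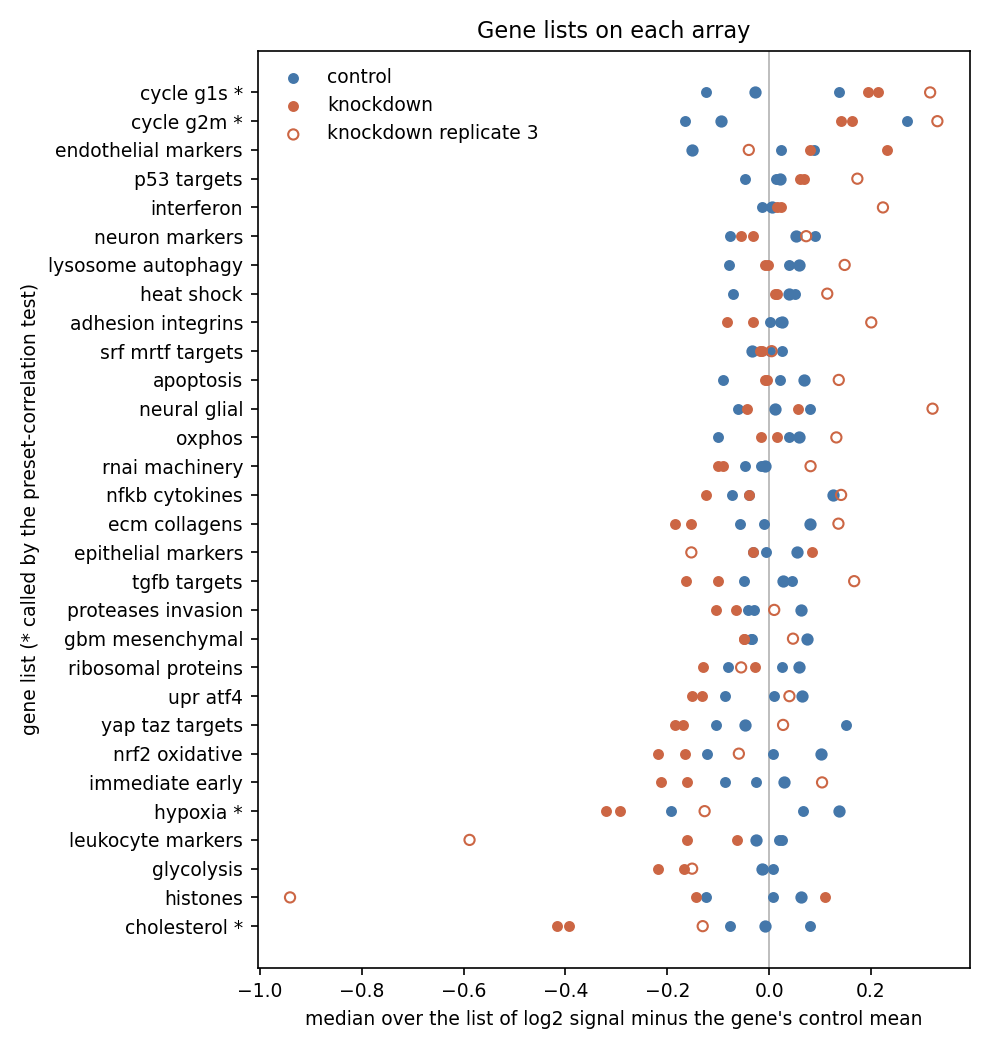
For 30 of the 31 gene lists, the median over its genes of the log2 signal minus the gene's control mean, with a point per array; open points are ROCK1 knockdown replicate 3 and stars mark the lists that passed camera with its preset correlation. Cholesterol genes lie lower on all knockdown arrays (-0.39, -0.42 and -0.13), and histone genes on knockdown replicate 3 (-0.94).

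The remaining 27 lists did not pass. Of 35 SRF/MRTF targets, none passed over all genes, and adjusted over the list alone TPM4 rose (log2 0.80) and MYH9 fell (log2 -0.79). Of 21 YAP/TAZ targets, CCN2 alone fell adjusted over the list alone (log2 -0.90, adjusted p = 0.0639 over all genes). The matrix list (37 genes) had COL6A1 lower in the same way (log2 -0.89), and the protease list (30 genes) ADAM17 (log2 -1.69). Of 38 integrin and focal adhesion genes, 30 TGF-beta targets and 35 immediate early genes, none passed by either adjustment.

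Among 38 apoptosis regulators, adjusted over the list alone, 4 rose and 4 fell, with CASP6 at 0.75 and the death receptor gene TNFRSF10B at -0.87. Among 29 NF-kappaB targets and cytokines LIF passed over all genes, and adjusted over the list alone 2 rose and 3 fell, with CSF2 at -1.44. In the list of 32 p53 targets 1 rose and 2 fell adjusted over the list alone, with TP53INP1 at -0.90. In the list of 45 unfolded protein response genes 2 fell in this way, with the amino acid transporter gene SLC7A5 at -0.87. Of 44 interferon-stimulated genes none passed by either adjustment (median 0.10, and 0.01 without knockdown replicate 3), nor did any of 24 heat shock, 27 NRF2, 59 ribosomal protein or 41 lysosome and autophagy genes. Camera called the NRF2 list (median -0.13, 22 of 27 below 0, adjusted p = 0.094) without knockdown replicate 3 (0.0225), with array weights (0.00568), without control replicate 1 (0.00493), with the deposited values (0.0287) and with the variance trend (0.0428), but not with an estimated correlation (0.879). Of 23 glycolysis genes 18 lay below 0 (median -0.18, adjusted p = 0.145 by camera, 0.0489 without knockdown replicate 3, 0.039 with the slide row as a block, which rests on knockdown replicate 1 alone, and 0.879 with an estimated correlation), and SLC2A1, which is also in the hypoxia list, fell adjusted over the list alone. The 51 respiratory chain genes had a median of 0.01 (adjusted p = 0.529 by camera). In the mesenchymal list (32 genes) none passed, in the neural and glial list (15 genes) GLUL fell adjusted over the list alone (log2 -0.65), and in the small RNA pathway list (18 genes) DGCR8 did (log2 -0.67). The 24 histone genes had a median of -0.25 (adjusted p = 0.145 by camera), which was -0.01 without knockdown replicate 3 and -0.46 without knockdown replicate 1, where camera called the list (adjusted p = 8.65e-04), as it did after quantile normalization (0.0407) and with the deposited values (0.0355), but not with an estimated correlation (0.879). Markers of other cell types did not pass as lists: medians were 0.10 for 11 neuron, -0.18 for 18 leukocyte, -0.03 for 16 epithelial and 0.13 for 12 endothelial markers, and -0.01, -0.06, 0.04 and 0.16 without knockdown replicate 3. Adjusted over the list alone, 1 neuron marker rose and 2 fell, and 1 endothelial marker (ICAM2, log2 0.69) rose. For the TGF-beta list the median (-0.03) and the mean (-0.05) lay below 0 while camera's direction was up. For the SRF/MRTF and neuron lists the mean was -0.02 while the median and camera's direction lay above 0.

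ROCK1 knockdown replicate 3 stood apart from the other arrays. Its genes correlated at 0.966 to 0.981 with the other 5 arrays, across genes, which are not independent replicates, while the other pairs lay between 0.984 and 0.995. The median absolute deviation of its genes from the mean of knockdown replicates 1 and 2 was 0.34 log2, beside 0.12 between those replicates. Its bright corner features read 14.4 log2, against 16.7 to 16.9 on the other arrays, and its 28S ribosomal RNA probes read 5.70 relative to the 75th percentile, against 7.88 to 8.64. All 6 arrays lay on 1 slide and came from 1 scan. Slide row 1 held the 3 control arrays and knockdown replicate 1, and row 2 held the other knockdown arrays; with the slide row as a block, which compares within row 1, 20 genes were called, all lower, of which 3 were among the 45, and the G2/M list lost its call (adjusted p = 0.109 by camera). Of these 20 genes, 15 were read only from the parts of the array described next.

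In the 30 bottom rows of the array, 3.49% of 4578 spots were lower by over 2 log2 in the knockdown mean, against 0.175% of 54139 spots elsewhere. Spot counts by position used signals that were not scaled between arrays, and flagged spots were kept. The 4 largest falls among the 45 called genes came from the bottom rows and had no gene symbol: ENST00000375130, ENST00000453496, ENST00000515150 and a long intergenic RNA on chromosome 14. None was well above background on any knockdown array. With those arrays set at the lowest signal well above background, these transcripts were 11.4-fold, 6.64-fold, 5.98-fold and 23.4-fold lower at these spots. Signals not well above background can lie above that level, as for ZNF875, so these folds are not strict lower bounds. The other probe of the chromosome 14 transcript was not well above background on any of the 6 arrays. A strip of 4 columns held 26 spots that were lower by over 3 log2 on knockdown replicate 1 than on the other arrays, and none on the others. Outside the strip, 75 spots were this low on knockdown replicate 3, against 3 to 8 on each of the other arrays. Of the 45 called genes, 9 (8 lower and 1 higher) were read only from the bottom rows and the strip. The remaining 36 (20 lower and 16 higher) were also called when these parts were left out. Of the 36, 34 had no spot there, so leaving the parts out says little about their calls.

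**Figure D4:**
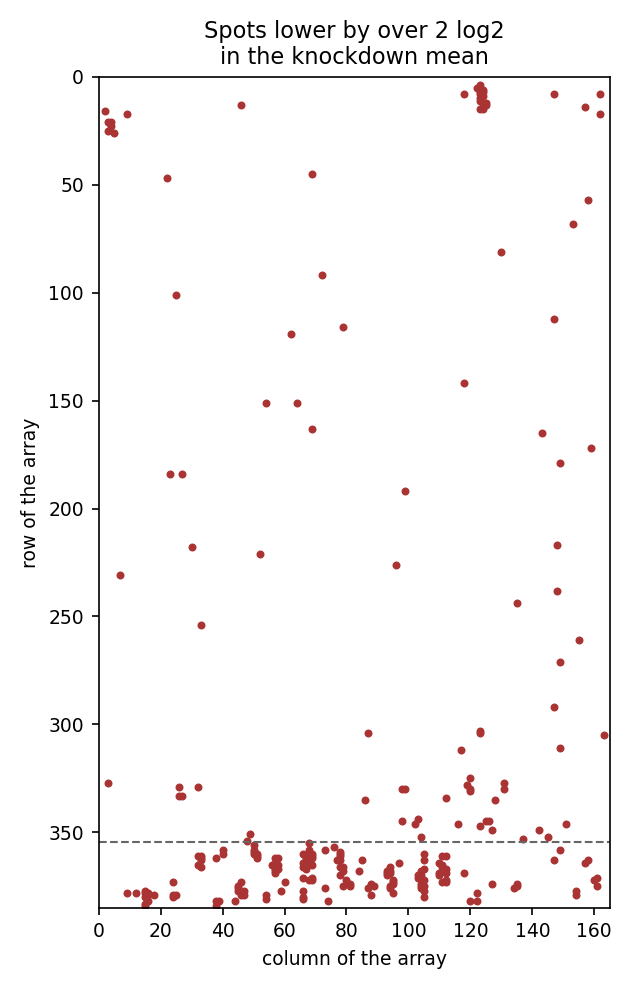
Position on the array, by row and column, of the spots whose mean log2 signal was lower by over 2 in the knockdown; the dashed line marks the start of the 30 bottom rows. The bottom rows hold 160 of these spots and all other rows 95. Signals were not scaled between arrays, and flagged spots were kept.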

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

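ROCK1 was lower in every alternative; no setting turned the direction of a named gene that passed or camera's direction for a called list. Of the alternatives, those that leave out parts of the array and the one with the slide row as a block were chosen after seeing the data. The cause of the changes below was not tested. The main count was 45 genes (17 higher, 28 lower, 39 at least 2-fold) and 4 lists. Normexp gave 150 genes (61, 89, 59), quantile normalization 108 (60, 48, 75), the authors' deposited values 192 (81, 111, 68), the filter on all 6 arrays 85 (41, 44, 61), and the variance trend with robust estimation 179 (75, 104, 103). Array weights gave 4192 (1814, 2378, 451), with weights of 0.151 for knockdown replicate 3 and 6.59 for knockdown replicate 2. Median centring gave 26 genes, 9 of them lower, and 2 lists. No filter gave 2 genes (0 higher, 2 lower, 2 at least 2-fold; 4577 at an unadjusted p under 0.05 in limma), with ROCK1 at -2.71 (adjusted p = 0.0538). An adjusted p under 0.01 left 3 genes (0, 3, 3), and under 0.1 437 (182, 255, 187). The slide row as a block gave 20 (0 higher, 20 at least 2-fold; 1268 at an unadjusted p under 0.05 in limma). Without the bottom rows and the strip of columns, 36 genes were called (16 higher, 20 lower, 31 at least 2-fold). Leaving out these parts and knockdown replicate 3 gave 287 (97, 190, 127). With single samples left out, the counts ranged from 2 to 224 genes, 0 to 77 higher, 2 to 147 lower, 2 to 119 at least 2-fold and 1 to 6 lists, and ROCK1 from -2.88 to -2.61, with adjusted p from 0.00284 (without knockdown replicate 3) to 0.0917 (without control replicate 3); it passed only without knockdown replicates 1 and 3. With an estimated correlation camera called 0 lists (0 at an unadjusted p under 0.05), and fry 0 (3 at an unadjusted p under 0.05).

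The replicate block gave 2 genes (0 higher, 2 lower, 2 at least 2-fold; 3902 at an unadjusted p under 0.05 in limma) and 4 lists, with ROCK1 at -2.71 (adjusted p = 0.16). The deviations from the group means correlated at -0.08, 0.01 and -0.08 for numbers 1, 2 and 3. Not every sample correlated best with its own number, so the values gave no sign of a pairing. With 3 samples in a group the deviations of a group depend on each other, so these correlations cannot exclude a pairing.

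The 23 named genes other than ROCK1 and ROCK2 stayed past the threshold in 247 of 480 recomputed values and kept the direction in all. The 4 called lists stayed called in 71 of 92. The other 27 lists became called in 13 of 621 values, and their direction differed in 51, none of them called. Signal over background limits the dim genes: the median spot was 2.74 to 3.29 times the negative controls.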

Other observations

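Of the tests below, those of the label and of the signal scale of knockdown replicate 3 and of the negative control spots were chosen only after the result was seen. Among the genes that rose were 3 zinc finger genes, ZNF616, ZNF721 and ZNF875. This led to the hypothesis that genes with a ZNF symbol were higher as a class in the knockdown. Of 335 such genes tested, 260 had a fold change above 0, 3 rose and none fell (limma). Their median log2 fold change was 0.22, above 100% of the medians of 10000 random lists of the same size matched on mean signal, of which the middle 95% lay between -0.09 and 0.01. Relative to each gene's control mean the class median was 0.23, 0.18 and 0.30 on the knockdown arrays and -0.05, 0.02 and 0.03 on the control arrays. Camera gave p = 3.87e-11 with the preset correlation and p = 0.022 with an estimated one. The median was 0.21 without knockdown replicate 3 and between 0.16 and 0.41 under the other scalings. In the 10 splits of the 6 samples the real one gave 0.22 and the highest other 0.13, but 10 splits are too few for a share under 0.05. The data are consistent with a small rise of the class, found and tested on the same samples; technical causes were not tested.

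Knockdown replicate 3 stood apart from the other 5 arrays, and the count of called genes rose from 45 to 224 without it. A wrong label in the sense that this array held no knockdown is argued against by ROCK1. It lay at -2.38 log2 relative to the control mean on this array. Other errors of labelling were not tested. A difference in scale that follows signal explained 5.12% of the variance of its deviations, under the 20% set as a bound. Its lower bright corner and 28S ribosomal RNA signals stay open, and no biological explanation was tested.

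The largest falls of called genes were read from the bottom rows of the array. Real falls of the RNA are argued against for the falls there of over 2 log2 that could be tested: 53 of these 160 spots had other spots of the same probe outside the bottom rows and the strip of columns, whose median log2 fold change was 0.077, with 1 of the 53 below -1. For the falls outside these parts 9 of 22 such values were below -1 (median 0.02). Falls without such other spots stay untested in this way. The spot values were not scaled between arrays and flagged spots were kept, so some of these spots may not have entered the comparison of genes. Of 23 negative control spots in the bottom rows, 14.5% were well above background on average on the control arrays and 4.35% on the knockdown arrays. Elsewhere it was 1.17% in both groups. The single control arrays read 26.1%, 8.70% and 8.70% and the knockdown arrays 4.35%, 0% and 8.70%, so the difference rests largely on control replicate 1. The ratio of 3.33 lies between the bounds set for and against local signal on the control arrays, and the spots are few, so this source of the falls stays open. Without these parts 36 of the 45 called genes remained past the threshold and the other 9 had no spot left. Of the 36, 34 had no spot there, so signal local to these parts did not make their calls. For the 9 it stays open. Falls of over 2 log2 also lay near the top edge of the array and just above the bottom rows. Local signal outside the excluded parts was not tested for the 36.

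The 4 called gene lists could follow a trend of fold change with signal. After a smooth curve on mean signal was taken off, all 4 stayed called, with medians of 0.19 for G1/S, 0.15 for G2/M, -0.32 for cholesterol and -0.23 for hypoxia genes, which argues against such a trend as the whole cause. The histone and NRF2 lists then passed as well (adjusted p = 0.0463 by camera for each). The correlation between genes stays open, since no list passed with an estimated one.

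In the 10 splits of the 6 samples into 3 and 3, only the real split (1) called any gene: 45 in all, 17 higher, 28 lower and 39 at least 2-fold, where the highest of the other splits was 0. For the gene lists, 6 of the 10 splits called at least 4, and the highest other called 14, with control replicate 1 and knockdown replicates 1 and 2 on one side, which points to a structure of the samples. In both cases 10 splits are too few for a share under 0.05.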
